A study of Mus musculus with 4 samples.

How the data were processed

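Total RNA from mouse hippocampus had been labelled with the dye Cy5, starting from 2.5 µg of RNA, with a chemical labelling kit and a size filter that enriches small RNA, per the labels' protocols. Each of the 4 arrays carried 1 sample. The series describes 4 mice per group and 2 replicate arrays per group. How the 4 mice of a group were divided over its 2 arrays is not given in the sources used here, so p-values measure only the spread between arrays, which may be technical.

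The deposited raw intensity values, per the file headers, are unnormalized spot brightness on a linear scale. They came with a deposited flag for each spot, either 0 or -50, and spots at -50 were about as bright as blank spots. The array had 2115 spots for 705 mouse miRNA probes, 3 spots per probe, and 105 spots for 19 control probes, 36 of them blank. A second table held the authors' normalized intensity for 383 probes, per the file headers, and the series value table repeated those values. The authors' log2 ratio column, per the file headers, set good over poor performers, and it equalled the log2 ratio of the group means of the normalized intensity to within 4.9e-05. The normalization method, software and array design are not given in the sources used here. From the values alone, the 383 probes were those with at least 1 spot at flag 0, all 4 arrays shared one 75th percentile, and the arrays of a group had almost the same sorted values.

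The raw intensity was corrected for background with the normexp model of limma 3.58.1 in R 4.3.3 (offset 50, fitted on all spots), taken to log2, quantile-normalized over the miRNA spots, and averaged over the 3 spots of a probe. Quantile normalization places spots on shared ranks, and ranks are sparse among the brightest probes, so their fold changes and standard deviations are coarse. An example is miR-2138, with a standard deviation of 0 between the good-performer arrays. A probe was tested if at least 2 of its 3 spots had flag 0 on both arrays of a group, which kept 316 probes. The use of the flag was fixed before the data were examined, and the requirement of 2 spots was set after the files were seen and before any test was run. A fold change is on the log2 scale with the offset, which understates changes of dim probes.

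Good and poor performers were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the 316 probes and a threshold of 0.05. With 2 arrays per group, an exact permutation test has 3 splits and cannot give a two-sided p under 0.333, so the variance model of limma carries the test. A total of 14 lists of miRNAs was fixed before the data were examined, and the 13 with at least 3 tested probes were tested with camera of limma at a preset correlation of 0.01 between probes. The value given for a list is its mean log2 fold change, with the median. camera compares a list with the other tested probes, so a list with a mean below 0 can still be placed higher. Alternatives were an estimated correlation and fry, which asks whether a list's members move one way on balance.

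The names in the text followed a rule fixed before the data were examined. It took the 8 probes with the largest change in each direction among those past the threshold whose arrays did not overlap, filled by lowest p. It added the 3 brightest tested members of each list, miR-466f-3p, miR-132, miR-212, miR-134 and miR-124 by name, and each member of a count of 5 or fewer. Other names were chosen after their values were seen. Probes whose name lists several miRNAs were kept as 1 probe.

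Before averaging, arrays of a group were compared over the 300 probes detected on all 4 arrays. Their differences had 2.68 times (good) and 2.34 times (poor) the variance that spot noise predicts, so they were not copies of 1 array and were counted as 2. This does not show that they came from separate animals, since repeat hybridisations of 1 pool can differ by more than spot noise. On simulated arrays with the spread of this comparison, 74.8% of probes changed by 0.25 log2 units were called, 93.5% at 0.5 and 98.3% at 1. Each simulated set changed 20 probes at each size, and its spread was drawn from limma's own fitted prior. Many changed probes loosen the adjusted threshold, and limma's variance model held by construction, so detection in the real data may be lower. Among unchanged probes 0.94% were called. Those simulated probes varied independently, which family members with shared sequence do not.

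Locations relative to the gene Sfmbt2 came from a RefSeq gene table of the mouse assembly GRCm38.p6, by gene symbol and synonym, and all 25 tested probes of the families concerned matched. No build is named for the array, so no coordinates are given. Alternatives covered the authors' normalized table, 75th percentile scaling, cyclic loess, no normalization, other offsets, other filters, the median over spots, a trended and robust variance model, a block for replicate number and leaving out each array. Added after the data were seen were scaling to spike-in controls, centring of the authors' table, leaving out saturated probes and 3 other scales for the control probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.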

Results

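Hippocampal miRNA was profiled in C57BL/6J mice, a common inbred laboratory strain, after training in the Morris water maze, a test of spatial learning in which a mouse swims to a hidden platform. Good performers (2 arrays) were set against poor performers (2 arrays), from tissue taken directly after training. The number of arrays limits the precision of every value. Between 310 and 330 of the 705 probes were detected per array (320 and 330 in good, 310 and 322 in poor performers). The median tested probe had a raw intensity of 160 to 165, about 2.5 times that of blank spots, whose mean was 63 to 64.

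The first comparison asked which miRNAs differed between good and poor performers. In good performers 10 probes were higher and 6 lower. Of the 10 higher probes, 9 belonged to the miR-466, miR-467 and miR-669 families, most of whose genes lie in a large cluster inside Sfmbt2, a Polycomb-related gene. The largest rise was that of miR-466f-3p, at 9.90 ± 0.033 (SD, n = 2) log2 intensity in good and 9.29 ± 0.0032 (SD, n = 2) in poor performers. That is a log2 fold change of 0.62 ± 0.03 (SE), or 1.53-fold (limma adjusted p = 0.0058). miR-467b* rose by 0.61 and miR-466i by 0.54. The probe shared by miR-467a-1* and miR-467d* rose by 0.51, miR-466g by 0.47, miR-669f by 0.46, miR-467f by 0.45, miR-467e* by 0.41 and miR-467g by 0.39. Of these 9 calls 5 were kept in the authors' normalized table and 5 with the median over spots, where miR-466g, miR-466i, miR-467f and miR-467g lost theirs in both. With offset 1, 6 were kept (miR-466g, miR-466i and miR-467g lost), and 8 in the centred authors' table (miR-467f lost). The 1 other probe that rose was miR-3473, by 0.21 (adjusted p = 0.041). Its call was lost with the replicate block (adjusted p = 0.063), with offset 1 (0.099) and with the median over spots (0.359). Its log2 fold change was 0.14 with the median over spots, 0.45 with 75th percentile scaling and 0.47 without normalization.

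The largest fall was that of miR-2133, at 9.29 ± 0.062 (SD, n = 2) in good and 9.93 ± 0.0092 (SD, n = 2) in poor performers. Its log2 fold change was -0.64 ± 0.04 (SE; limma adjusted p = 0.0065). miR-2137 fell by 0.50, miR-219 by 0.27, miR-691 by 0.27, miR-762 by 0.26 and miR-711 by 0.21. The calls of miR-219 and miR-711 were lost with 75th percentile scaling, without normalization, with offset 1, with the median over spots and in the centred authors' table, and that of miR-711 also without a filter and with the replicate block. The call of miR-762 was lost without normalization, with offset 1, with the median over spots and with the replicate block, that of miR-691 in the last 3 of these, and that of miR-2137 with offset 1 and with the median over spots. Of the 6, miR-2133 alone kept its call in every setting with all 4 arrays. The log2 fold change of miR-219 ranged from -0.30 to -0.16 over the settings tried. Ranges were -0.39 to -0.14 for miR-691, -0.43 to -0.19 for miR-762 and -0.28 to -0.13 for miR-711. miR-219 promotes the maturation of oligodendrocytes, the myelin-forming cells. The next probes by p in this direction did not pass: miR-1902 had a log2 fold change of -0.26 and miR-2138 of -0.15 (adjusted p = 0.074 and 0.076).

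The 16 calls were made at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 66 probes, against 15.8 by chance, and the 2 groups did not overlap in 50.6% of probes, against 33.3% by chance. Both chance values are averages. Probes share the same 4 arrays and can move together, so the excess alone does not show more than a difference between arrays. No probe passed when any 1 of the 4 arrays was left out (limma; 41 to 57 probes at an unadjusted p under 0.05), and none had an absolute log2 fold change of 0.8. The split of 10 higher to 6 lower was 6 to 31 in the authors' normalized table, 16 to 6 with 75th percentile scaling, 12 to 3 without normalization and 10 to 21 with spike-in scaling. It was 11 to 4 in the authors' table after centring each array. In the authors' deposited table the log2 ratio of miR-466f-3p was 0.56, the highest of 383, and that of miR-2133 was -0.67, the lowest.

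**Figure D1:**
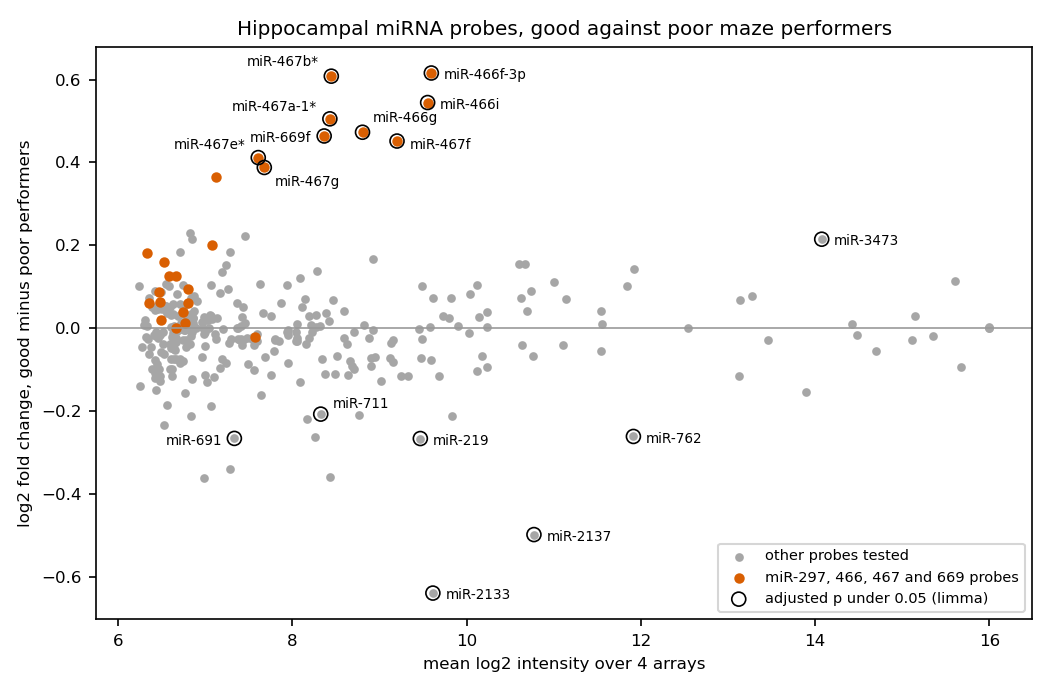
Log2 fold change (good minus poor performers) against mean log2 intensity over 4 arrays, 1 point per tested probe (316). Orange points are miR-297, miR-466, miR-467 and miR-669 probes, and rings mark limma adjusted p under 0.05; 9 of the 10 ringed points above 0 are orange, and none of the 6 below 0 is.

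The second comparison concerned the miR-297, miR-466, miR-467 and miR-669 families as a list. It is the study's own focus and not independent evidence. Of 48 probes on the array 25 were tested, 9 rose, none fell, and 24 had the higher mean in good performers. Adjusted over the list alone, 11 rose. The mean log2 fold change was 0.24 (median 0.16; camera adjusted p = 2.0e-12). With an estimated correlation between members of 0.32 the call was lost (camera p = 0.094 unadjusted and 0.725 adjusted). Several lists share that adjusted value, since the adjustment gave lists of unlike p the same value. The alternative fry gave an adjusted p of 0.055. The mean log2 intensity of the list was 7.53 ± 0.034 (SD, n = 2) in good and 7.28 ± 0.020 (SD, n = 2) in poor performers. Members with a higher mean numbered 17 of 25 in the authors' normalized table and 14 of 25 with spike-in scaling, where the median of all tested probes was -0.11, while the list mean stayed above 0 in both (0.17 and 0.14). Without a filter on dim probes the mean fell to 0.12 and the median to 0.05 over 48 probes, of which 35 had the higher mean, and with offset 200 the mean was 0.16. By family, the mean log2 fold change was 0.42 for 6 miR-467 probes, 0.22 for 11 miR-466 probes, 0.11 for 7 miR-669 probes and 0.36 for the 1 miR-297 probe, which did not pass alone (adjusted p = 0.057). The members that did not pass were mostly dim, and miR-669c, of higher intensity, had a log2 fold change of -0.02. Control probes for U2 small nuclear RNA were also higher in good performers, by 0.50 and 0.44 log2 units, as was the spike-in control 1, by 0.24 (limma; adjusted p over controls = 2.1e-04, 0.0015 and 0.0088).

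**Figure D2:**
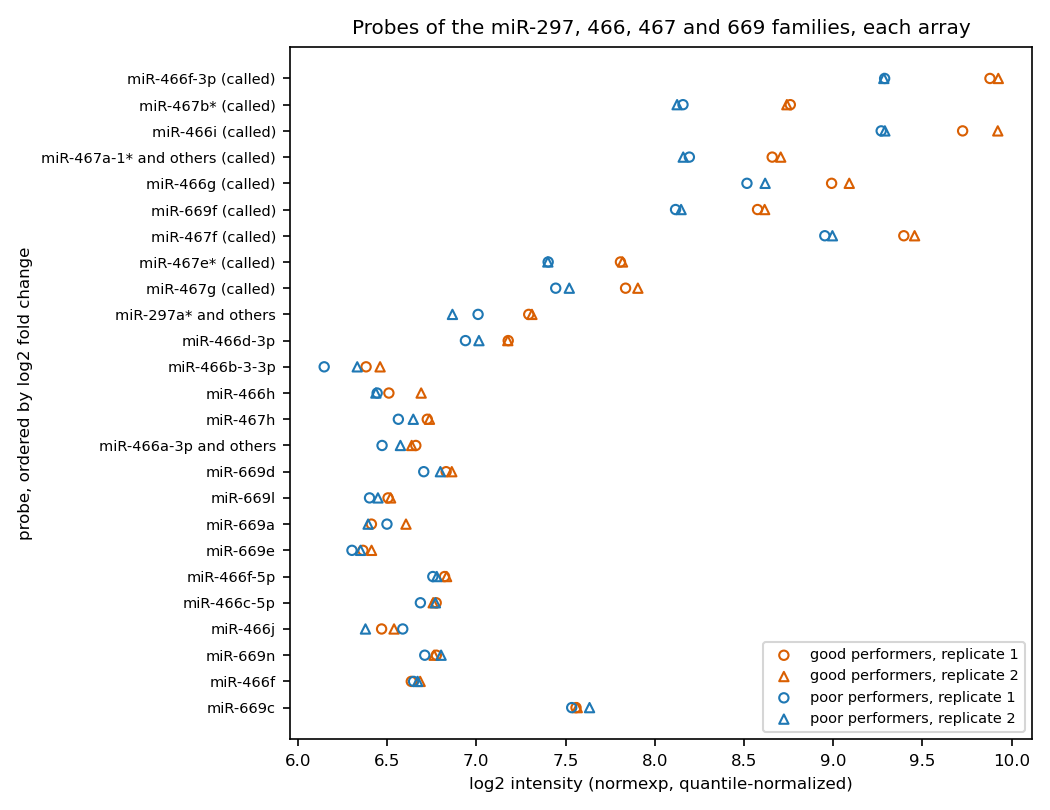
Log2 intensity of each tested probe of the miR-297, miR-466, miR-467 and miR-669 families on each of the 4 arrays, ordered by fold change. Both good-performer arrays lie above both poor-performer arrays for 19 of the 25 probes, among them the 9 called, and many of the rest lie close to the floor of the scale.

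The third comparison concerned 28 tested miRNAs with known roles in memory or synaptic plasticity. None passed (limma; 0 also adjusted over the list alone, 5 at an unadjusted p under 0.05), and the list mean was 0.01 (median 0.01; camera adjusted p = 0.394). miR-132 and miR-212, which are transcribed from one locus under the control of the transcription factor CREB, had log2 fold changes of 0.09 and 0.06 (adjusted p = 0.209 and 0.375). miR-134, which limits the size of dendritic spines, had -0.02, and the neuronal miR-124 had 0.01. Among the brightest members miR-128 had 0.14 and miR-29a 0.10 (adjusted p = 0.154 and 0.193). The list mean was -0.05 in the authors' normalized table and -0.08 with spike-in scaling, and it passed in neither. Relative to the other probes, camera placed the list higher in both.

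The remaining lists held cell type markers, genomic clusters and RNA classes, and none passed (limma camera). Markers of oligodendrocytes had a mean of -0.14 and a median of -0.09 over 3 probes (adjusted p = 0.079), and passed without a filter on dim probes and without poor performers replicate 2 (mean -0.18, adjusted p = 0.035). Without each of the other 3 arrays it did not pass (adjusted p = 0.176, 0.276 and 0.319), nor in the authors' normalized table (0.483) or with spike-in scaling (0.425). With an estimated correlation the camera p was 0.249 unadjusted and 0.725 adjusted. The list mean was -0.09 with 75th percentile scaling, -0.07 without normalization and -0.06 in the centred authors' table. It was -0.15 in the authors' normalized table and -0.21 with spike-in scaling. Of the 3 oligodendrocyte probes miR-219 fell, while miR-338-3p and miR-338-5p had log2 fold changes of -0.07 and -0.09 and did not pass. All 10 astrocyte probes had a higher mean in good performers (list mean 0.05, median 0.04, adjusted p = 0.074). Examples are miR-26a at 0.11, miR-29a at 0.10 and miR-29b at 0.01. That list passed with 75th percentile scaling, without normalization and without a filter on dim probes (means 0.09, 0.11 and 0.04). In the reported setting with an estimated correlation, the camera p was 0.130 unadjusted and 0.725 adjusted. A higher mean held for 6 of the 10 in the authors' normalized table and for 2 with spike-in scaling, and the list mean was below 0 in both. The median of all tested probes was lower still there (-0.08 and -0.11), and camera placed the list above the other probes in both. It passed in neither, nor without any 1 array. The 17 neuronal probes had a mean and a median of -0.01, with miR-138 at -0.06. Of the 16 probes upstream in the imprinted Dlk1-Dio3 region 13 had a lower mean (list mean -0.06, median -0.05, adjusted p = 0.074), among them miR-665 at -0.22, miR-127 at -0.10 and, on the other side, miR-136 at 0.01. Without normalization 7 of these 16 had a higher mean. That list had a mean of -0.14 in the authors' normalized table and of -0.17 with spike-in scaling. It passed with 75th percentile scaling, without normalization, without a filter and in the centred authors' table (means -0.05, -0.03, -0.05 and -0.05). It also passed without good performers replicate 1 (mean -0.08, adjusted p = 0.018) and without poor performers replicate 2 (mean -0.07, adjusted p = 0.049). It did not pass without good performers replicate 2 (mean -0.04, adjusted p = 0.276) or without poor performers replicate 1 (mean -0.06, adjusted p = 0.244), nor in the authors' normalized table (0.068) or with spike-in scaling (0.236). With an estimated correlation its camera p was 0.304 unadjusted and 0.725 adjusted. The miR-379 to miR-410 cluster of the same region had a mean of -0.03 (median -0.02) over 25 probes, with miR-300 at -0.11, miR-494 at 0.07 and miR-382 at 0.01.

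No list for cells that a dissection could also hold passed. The microglial and immune list had a mean of -0.0034 and a median of -0.01 over 3 probes (miR-146b 0.04, miR-150 -0.01, miR-21 -0.04). The vascular list had a mean of -0.01 and a median of -0.03 over 5 (miR-145 -0.02, miR-143 -0.03, miR-126-5p -0.09), and its largest member, miR-214, had 0.18 (adjusted p = 0.196). The choroid plexus and ependymal list had a mean and a median of -0.02 over 5 (miR-204 -0.02, miR-34b-5p -0.02, miR-141 -0.03). The erythroid list held 2 tested probes, too few for a list test, with log2 fold changes of -0.06 for miR-486 and -0.09 for miR-451 (-0.14 and -0.21 in the authors' normalized table). Without a filter on dim probes it held 3, with a mean of -0.23 and a median of -0.09 (adjusted p = 0.264), so a difference in blood content stays open. The let-7 family had a mean of -0.0019 and, with the other sign, a median of 0.0035 over 9 probes (let-7b 0.15, let-7c 0.07, let-7a 0.04). The miR-17 family clusters had a mean of -0.02 and a median of -0.04 over 9 (miR-106b 0.02, miR-93 0.00063, miR-92a* -0.08). Entries whose sequence overlaps ribosomal or transfer RNA had a mean of -0.07 and a median of -0.02 over 11 probes (camera adjusted p = 0.499). With fry this list had an adjusted p of 0.055, the same as the miR-297, miR-466, miR-467 and miR-669 list. Of the 11 probes miR-2133 alone fell. The probe for miR-1937a and miR-1937b had 0.11 and miR-2146 -0.02. Over the list alone miR-2138 passed too. miR-2145 was saturated on every spot except 2 of 1 poor-performer array, so its fold change is not read as a measurement.

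**Figure D3:**
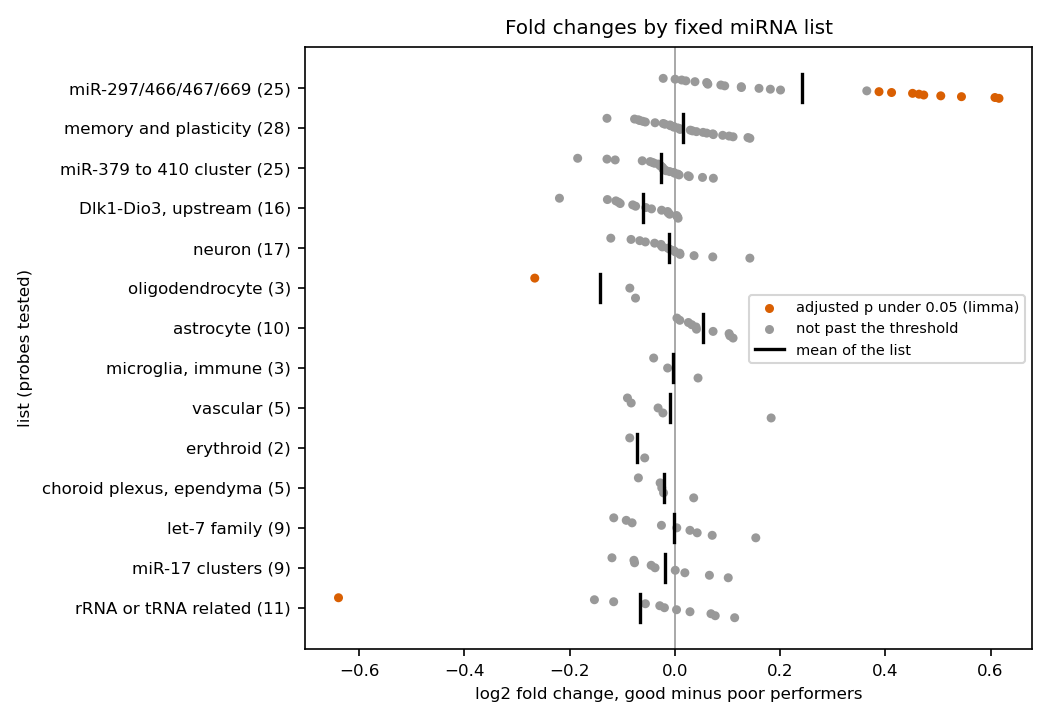
Log2 fold change (good minus poor performers) of each tested probe in 14 fixed lists, with the number tested in brackets and a black bar at the list mean; points are offset vertically for visibility. Orange points passed limma's adjusted p of 0.05: 9 in the miR-297, miR-466, miR-467 and miR-669 list, 1 of 3 oligodendrocyte probes and 1 of 11 ribosomal or transfer RNA related probes.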

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

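All tests in this part were chosen after the results were seen. The scale for the control probes was also chosen then: they were first placed on the miRNA quantile scale by interpolation, and were moved to 75th percentile scaling once that output had been seen, because miRNA spots are sparse at the brightness of the controls. Control probes, which are not among the 316 probes compared, differed between groups for 5 of 19 probes (limma, adjusted over controls). U2 small nuclear RNA was higher in good performers by 0.50 and 0.44 log2 units on its 2 probes, the U4 probe u4human.fish by 0.30, spike-in control 1 by 0.24 and m-3b by 0.20. On the scale used first, 3 passed (both U2 probes and spike-in control 1), and u4human.fish and m-3b had adjusted p of 0.097 and 0.086. Without normalization 4 passed, and with scaling to the spike-in mean 2 passed, both U2 probes.

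Brighter hybridisation or scanning of the good-performer arrays would raise added spike-in RNA as much as U2. The U2 mean exceeded the highest spike-in by 0.23 ± 0.06 (SE), and by 0.16 ± 0.06 on the scale used first, which argues against brightness alone for U2. For U4 the mean over both probes minus the highest spike-in was -0.013. The probe u4human.fish had 0.30, while RNA U4 had 0.16 and did not pass (limma adjusted p over controls = 0.087). The spike-ins nearest to each in brightness differed by less, spike-in control 3 by 0.16 and spike-in control 5 by 0.03. Whether brightness accounts for U4 is therefore left undecided. A difference between the groups in U2 content of the labelled RNA stays open and was not tested further. The 5 spike-ins themselves ranged from 0.03 to 0.24, and from -0.10 to 0.30 on the scale used first. That 0.30, of spike-in control 1, was larger than some called changes. These were miR-3473 (0.21), miR-711 (-0.21), miR-762 (-0.26), miR-691 (-0.27) and miR-219 (-0.27). Differences of that size therefore also arose in added RNA.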

How the results depend on the processing

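The spike-in scaling, the centred authors' table, the set without saturated probes and the scales for control probes were added after the data were seen. The 16 calls became 37 in the authors' normalized table, 31 with spike-in scaling, 30 with a trended and robust variance model, 7 with offset 1 and 6 with the median over spots. There were 0 at an unadjusted p under 0.05 with a log2 fold change of 0.8, and 0 to 0 when 1 array was left out, where fewer degrees of freedom remain and the lone array is assumed to vary like the other group. Of the 16, the same probes called numbered 12 in the authors' table, 13 in it after centring, 14 with 75th percentile scaling, 13 without normalization, 7 with offset 1, 6 with the median over spots, 12 with the replicate block, 15 without a filter, 0 without 1 array and 16 in the other 6 refits. The cause of the other changes was not tested. The mean of the miR-297, miR-466, miR-467 and miR-669 list was 0.24 and lost its call with an estimated correlation. It was 0.28 with families averaged first, 0.16 with offset 200, 0.12 without a filter (48 probes) and 0.215 to 0.266 without 1 array. Lists past the threshold numbered 3 with 75th percentile scaling, 3 without normalization, 4 without a filter, 2 in the centred authors' table and 1 to 3 without 1 array. They numbered 0 with an estimated correlation and 0 with fry (0 and 4 lists at an unadjusted p under 0.05). With the replicate number as a block, 13 probes passed. Deviations of same-numbered arrays correlated at 0.18, and with 2 pairs the numbers were not taken as pairing. Control probes past the threshold numbered 3, 4 and 2 on the other scales, against 5. Of 988 values of single named probes, 877 stayed on their side of the threshold, 100 lost their call, 10 gained one, and 1 reversed: miR-2145, at -0.11 in the authors' table, a value not read as a change because the probe was saturated. Among the 877, 82 uncalled values changed sign. The series' value table was not run separately, being identical to the normalized table, nor were miRNA probes of other species, since all 705 are mouse. The variance model does not act on camera. Signal about 2.5 times blank limits the dim probes.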

Other observations

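All tests in this part were chosen after the results were seen, except that the miRNA lists were fixed before the data were examined. Within the miR-297, miR-466, miR-467 and miR-669 families, 15 of the 25 tested probes read miRNAs with genes only inside Sfmbt2, and 5 of these rose. Genes only outside Sfmbt2, on other chromosomes, belonged to 6 probes, of which miR-466i, miR-467f and miR-467g rose. Another 4 had genes in both places, and miR-466f-3p rose among them. The mean log2 fold change was 0.26 outside and 0.23 inside, a difference of 0.03 (exact permutation p = 0.796, two-sided). That p treats related probes on the same 4 arrays as independent and does not measure spread between arrays or animals.

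The rise of these families was set against technical explanations. The rise went beyond that of other probes of like intensity, since 0 of 10000 random lists matched on intensity had a mean as high (the highest was 0.03). Quantile normalization itself holds such lists near 0, so this does not test intensity-dependent bias separately. Their probes were also drawn independently, while the family members had an estimated correlation of 0.32. Means of the random lists therefore spread less than those of a correlated list would. The 3 called members outside Sfmbt2 argue against transcription of Sfmbt2 alone if each probe read only its own miRNA. That count was 0 in the authors' normalized table, with the median over spots and when any 1 array was left out, and 1 with offset 1, while their log2 fold changes were 0.22 to 0.64 over all settings (0.50, 0.39 and 0.31 in the authors' table). Shared sequence read by several probes could give such a joint rise. The mean of 0.26 in members outside Sfmbt2 does not decide this, since a true change of those miRNAs would give it too. Probe sequences were not used here, so a rise of 1 or a few abundant members and a rise of many stay open, as does a difference between good and poor performers in these miRNAs.

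Of the 383 deposited ratios in the authors' normalized table, 318 were below 0, with a median of -0.08. Sorted values of replicate 1 of good and of poor performers differed there by a median of 0.080 log2 units. Between the arrays of a group the median gap was 0 (good) and 5.9e-04 (poor). The 37 calls in that table, 6 higher and 31 lower, include this gap between groups. All 4 arrays of that table share the same 75th percentile, so a true uniform shift of all miRNAs would not show in it. With 75th percentile scaling of the raw intensity, the median of the tested probes was 0.012. This scaling also removes a uniform shift, so the 0.012 is no test of one. It shows only that 75th percentile scaling of the raw intensity did not give the -0.08. Whether all miRNAs truly shifted stays open. The median log2 fold change of the tested probes was 0.031 without normalization but -0.11 with spike-in scaling. The spike-ins were brighter than the median tested probe. Without normalization the dimmest, spike-in control 5, differed by 0.05 and the brightest, spike-in control 1, by 0.26. The -0.11 therefore leans on the brighter spike-ins. A first test by centring each array was dropped after its result was seen, since centring removes any such shift by construction. The test given here replaced it with these medians already seen.

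One hypothesis was that the rise was confined to 1 strand of the hairpins. Probes named 3p or star had a mean of 0.38 (8 probes) and those named 5p 0.05 (2 probes), a difference of 0.33 (exact permutation p = 0.044, two-sided, 45 splits). Left out were 15 probes with no strand in their name, 5 of them called. The 5p probes lay as little as 0.74 log2 units above blanks, where the offset compresses changes, so a strand difference and low signal cannot be told apart. Still dimmer 3p probes, miR-466b-3-3p and that shared by miR-466a-3p and others, had 0.18 and 0.13 and did not pass.

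A second hypothesis was that strands of a hairpin change together. Across 34 hairpins outside these families, which are not independent replicates, Pearson's r was -0.18 (permutation p = 0.290, adjusted 0.581) and Spearman's rho 0.0032 (p = 0.986, adjusted 0.986). Without the 2 hairpins farthest from the median, r was 0.16, so its sign rests on them. The bound first set, an r under 0.2 with p above 0.05, was met and would have counted against the hypothesis. It was made stricter after r had been seen, because a p that misses the threshold excludes nothing, and the question is left undecided. This prediction was first marked as written before the data were seen, and was marked again as written after, because fold changes of some of these strands, though not r, had been seen.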
